A study of Homo sapiens with 42 samples.

How the data were processed

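RNA of A375 melanoma cells was measured on 42 Affymetrix whole-genome arrays, 1 per sample, from cultures of 27000 cells per the labels' protocols. The deposited table holds a signal intensity on the linear scale for 54675 probe sets on each array, computed in Affymetrix Expression Console per the submitters' processing notes, which give no version. The mean of each array after trimming 2% at each end was the same in all arrays, which was checked in the table. The deposited table gives neither detection calls nor scan dates, so that no background correction, scan batch or slide could be tested here. Signal ranged up to 11983.8, and 147 values of 0 were raised to the lowest positive signal, 0.1, before log2 was taken.

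Probe sets were named from GEO's platform annotation. Of the probe sets, 41091 carried 1 gene symbol, 1801 several, 11721 none in the annotation, and 62 were control probe sets. An Entrez identifier matched the gene table for 41037 of them, and 0 symbols needed an update. Each of 19775 genes was represented by its probe set with the highest mean signal, 10523 genes having more than 1, and probe sets with several symbols were left out. The median log2 signal of genes ran from 5.63 to 6.35 between arrays. A rule fixed beforehand made median centring the main setting where these medians differed by over 0.1, so each array was centred on its median gene. The deposited scaling without centring became an alternative chosen after seeing the data.

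The labels gave 14 groups of 3 arrays. GL2 and p53 siRNA have a first and a second set of DMSO arrays, told apart by an ending of the sample titles, and the labels do not say which set belongs to which treatment. 107 genes that differed between the sets placed every other array on a scale from the first set to the second. A group whose arrays all lay under 0.35 was compared with the first set, one whose arrays all lay over 0.65 with the second, and any other with both pooled, provided at least 50 genes differed. By this rule the Nutlin and daunorubicin groups were compared with the first set, and MLN4924 in GL2 and p53 siRNA cells, CDT1 siRNA and BRCA1 siRNA under DMSO with both. MLN4924 in CDT1 or BRCA1 siRNA cells was compared with the DMSO arrays of the same siRNA.

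Tests used limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes on 1 fit of all 14 groups and 28 residual degrees of freedom. The 20 comparisons were 20 contrasts of this fit, including tests of the difference between changes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its comparison with a change of at least 1.5-fold. The number of arrays limits the precision.

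The 21 gene lists were p53 targets, NRF2 targets, DNA replication and E2F targets, mitosis, homologous recombination and Fanconi repair, replication-type histones, NF-kB targets, hypoxia targets, ATF4 and the unfolded protein response, interferon-stimulated genes, melanocyte lineage, MAPK output, immediate early genes, sterol and fatty acid synthesis, cullin-RING ligases and neddylation, proteasome subunits, ribosome biogenesis, the BCL2 family, and markers of epithelial cells, fibroblasts and leukocytes. They hold 519 genes, of which 479 were measured. Each list was tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 21 lists.

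The comparisons, lists, control set rule, thresholds, alternatives and the rule for named genes were chosen before the data were examined. That rule names CDT1, BRCA1, CDKN1A and MDM2 where they are discussed. It names the 6 largest called increases and decreases for each drug in GL2 cells and 4 each in other comparisons, from genes whose arrays lay apart. It further names up to 4 members of each list with the largest moderated statistic. Fewer genes, and not every list, are printed for length.

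The alternatives chosen with them were the replicate number as a block, within all arrays and within control sets, other DMSO sets as control, quantile normalization, the mean of all probe sets of a gene and a pseudocount of 16. They also comprised leaving out dim genes, a fit of only the groups compared, limma's trend and robust options, array weights, other thresholds, and leaving out each array in turn. A comparison was further repeated without the doubted libraries, an alternative chosen after seeing the data. Overlaps of comparisons with shared controls were set against 20 simulations.

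The fit was tested on simulated data for Nutlin in GL2 cells, with 67, 67 and 66 of 19775 genes changed 1.5-fold, 2-fold and 4-fold. It recovered 22.4%, 62.7% and 80.3% of these, and called 7 of 19539 unchanged genes. Of the 21 lists it called only the shifted list. This says little on false calls of lists whose genes correlate, as estimated for mitosis (0.57). Tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.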

Results

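Gene expression was measured on 42 whole-genome arrays of A375 cells, a human melanoma line with an activated BRAF oncogene and functional p53. The cells had been transfected for 48 hours with an siRNA against p53, CDT1 or BRCA1, or with GL2, an siRNA against firefly luciferase that is commonly used as a control without a human target. They were then exposed for 26 hours to 0.065% DMSO, 650 nM MLN4924, 5 uM Nutlin or 100 nM daunorubicin. MLN4924 inhibits the NEDD8-activating enzyme and thereby the cullin-RING ubiquitin ligases, whose substrates include CDT1, a protein that licenses replication origins, and NRF2, the regulator of antioxidant genes. Nutlin keeps MDM2 from binding p53, and daunorubicin is an anthracycline that poisons topoisomerase II and breaks DNA. The labels give 14 groups of 3 arrays. GL2 and p53 siRNA were each combined with all 4 treatments, with DMSO in 2 sets, and CDT1 and BRCA1 siRNA with DMSO and MLN4924. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

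CDT1 and BRCA1, each the target of an siRNA, were examined first in every array. CDT1 had a log2 signal of 8.70 to 9.16 in the first GL2 DMSO set and 8.56 to 8.78 in the second, against 6.51 to 6.77 in CDT1 siRNA with DMSO and 6.07 to 6.26 in CDT1 siRNA with MLN4924. BRCA1 lay at 8.88 to 8.95 and 8.52 to 8.70 in the GL2 DMSO sets and at 5.82 to 5.98 in BRCA1 siRNA with DMSO. CDKN1A, the p53 target that encodes the cyclin-dependent kinase inhibitor p21, was 9.01 to 9.25 in both GL2 DMSO sets and 6.48 to 7.57 in the p53 siRNA DMSO sets. A pair of MLN4924 libraries went against their labels. The library labelled replicate 3 of GL2 with MLN4924 had BRCA1 at 4.70, the others of its group 7.95 and 8.24. That labelled replicate 3 of BRCA1 siRNA with MLN4924 had 8.18, the others 4.93 and 5.28. CDT1 differed in the same pair, at 7.27 against 8.81 and 8.86 in the GL2 group. In the BRCA1 group it lay at 8.61 against 7.27 and 7.31. Both stayed in the groups their labels give. The fit shares a gene's spread between all groups, so the pair widens BRCA1's standard error and raises its p in every comparison. No 2 arrays were duplicates. The closest, replicates 2 and 3 of p53 siRNA with DMSO, had a median absolute log2 difference of 0.169.

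**Figure D1:**
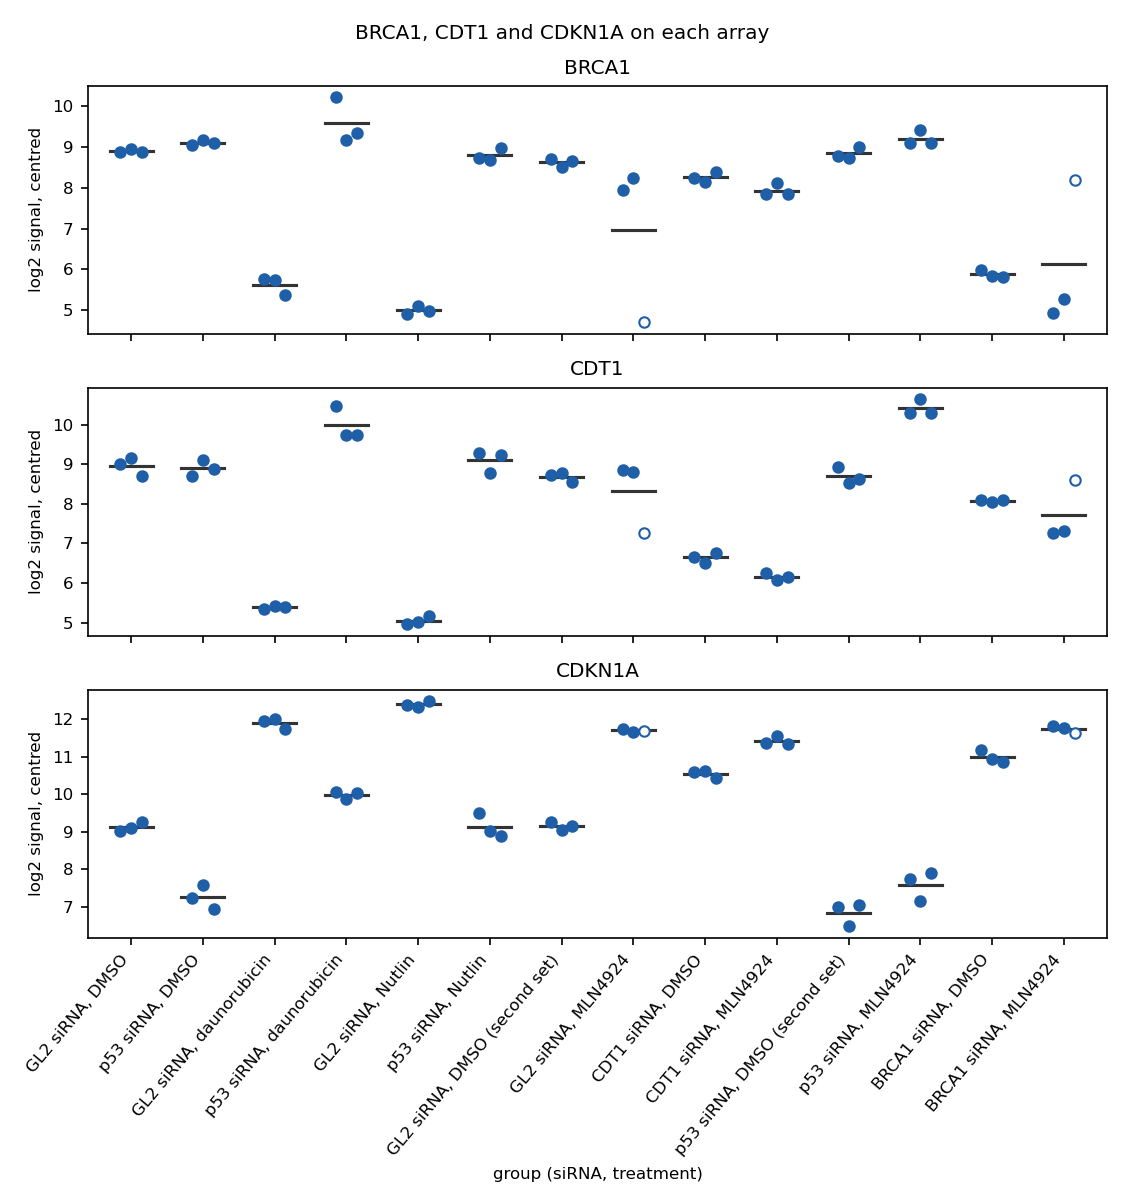
Log2 signal of BRCA1, CDT1 and CDKN1A on each of the 42 arrays (vertical axis, median-centred arrays), by group (horizontal axis), with a point per array and a line at the group mean. Open points are the libraries labelled replicate 3 of GL2 (BRCA1 at 4.70) and BRCA1 siRNA (8.18) with MLN4924.

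RNA quality differed for 1 library. The library labelled p53 siRNA with daunorubicin, replicate 1, had a ratio of 5' to 3' signal of 0.0118 for actin (ACTB) and 0.0509 for GAPDH, where the other 41 arrays had 0.649 to 0.945 and 0.989 to 1.19. This library and the pair with unexpected BRCA1 levels are called the doubted libraries here, and values without all 3 of them were computed as an alternative chosen after seeing the data. The actin ratio was also lower on Nutlin and daunorubicin arrays of GL2 cells, 0.697 to 0.732 and 0.727 to 0.769, than in the first GL2 DMSO set, 0.806 to 0.886. In p53 siRNA cells it was 0.721 to 0.821 with Nutlin and 0.649 and 0.727 on the other daunorubicin arrays, against 0.859 to 0.885 in the first p53 DMSO set.

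**Figure D2:**
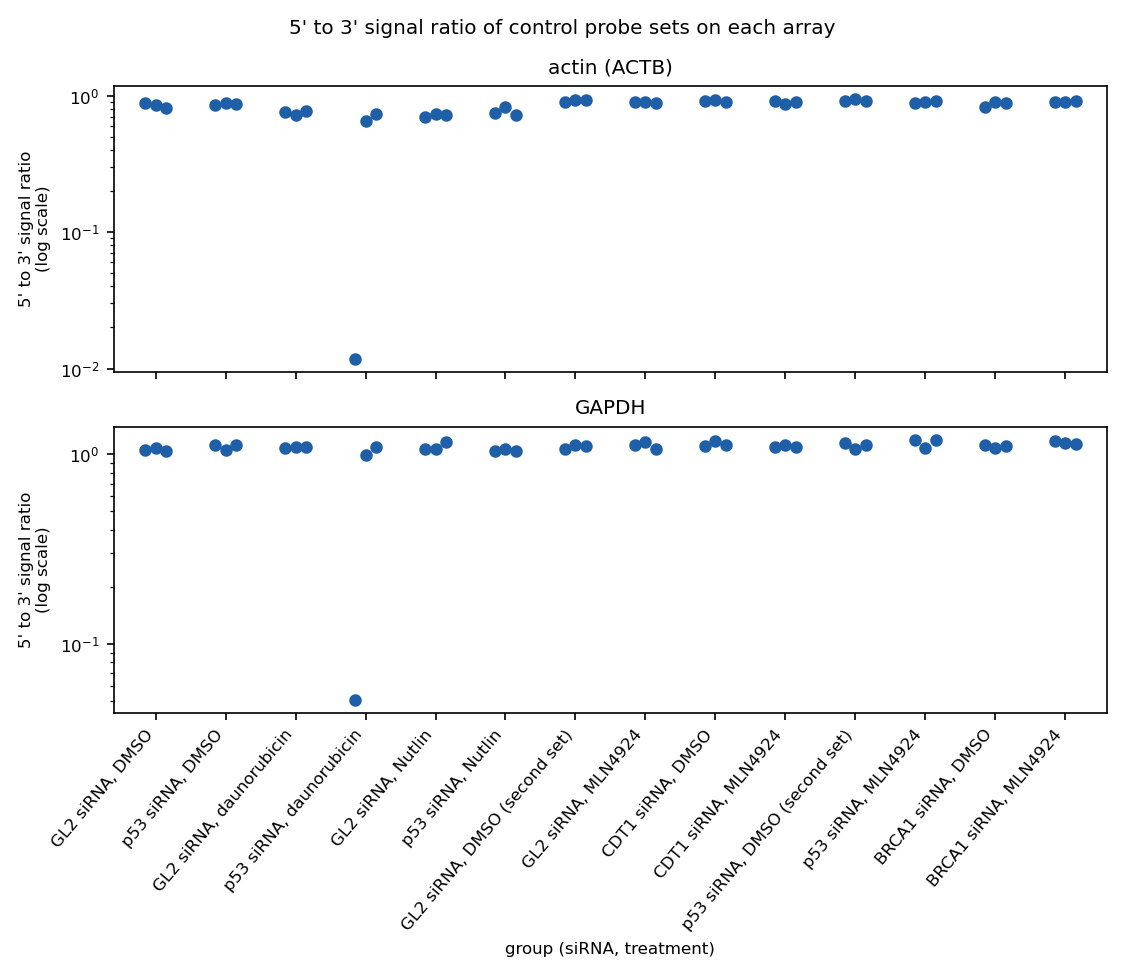
Ratio of 5' to 3' signal of the actin and GAPDH control probe sets (vertical axis, log scale) on each of the 42 arrays, by group (horizontal axis), with a point per array. Replicate 1 of p53 siRNA with daunorubicin lies at 0.0118 for actin and 0.0509 for GAPDH, and the other 41 arrays at 0.649 or higher.

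Changes are log2 differences ± the standard error of limma's fit, and a gene was called at an adjusted p under 0.05 with at least 1.5-fold. Arrays were centred on their median gene, which moved the median change of all genes with MLN4924 by 0.18 in GL2, 0.42 in p53, 0.11 in CDT1 and 0.18 in BRCA1 siRNA cells. The shift was -0.13 for Nutlin in GL2 cells, -0.14 for Nutlin in p53 siRNA cells and -0.17 for daunorubicin in GL2 cells. It was 0.23 for the MLN4924 difference between p53 and GL2 siRNA, 0.31 and 0.35 for MLN4924 less Nutlin and less daunorubicin, and at most 0.10 in size elsewhere. All changes are therefore relative to the median gene, and splits at the deposited scaling stand beside the counts of genes. List counts at that scaling, or without the doubted libraries, are given where either moved by over 1.5 times and at least 2 genes. "Dim" marks a called gene whose lower group, or in a difference of changes any group, lay under a signal of 31.9, the median of all values, so that the size of its change depends on the background signal. Single libraries are written by group and replicate, as in p53 DMSO 2. Where no counts adjusted over the list alone are given, they were equal. Where only 1 camera p is given for a called list, the call held with an estimated correlation, often at a far larger p. With MLN4924 in GL2 cells it was 3.0e-04 for p53 targets and 0.0157 for mitosis, and 0.031 for mitosis in the p53 siRNA difference.

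MLN4924 in GL2 siRNA cells raised p53 targets and antioxidant genes and lowered genes of mitosis. Among p53 targets, 32 of 37 rose and 0 fell (median 1.64, camera adjusted p = 1.4e-31). These included CDKN1A (2.57 ± 0.15, adjusted p = 1.9e-14), MDM2 (1.94 ± 0.14), SESN1 (2.26 ± 0.12) and FAS (2.59 ± 0.14), a death receptor. Of the NRF2 targets, 15 of 24 rose and 0 fell (median 0.96, camera adjusted p = 7.1e-11). Among them were AKR1B10 (3.21 ± 0.12), SRXN1 (2.06 ± 0.14), TRIM16 (1.55 ± 0.13) and TXNRD1 (1.28 ± 0.12), which encodes thioredoxin reductase. Among mitosis genes 35 of 36 fell and 0 rose (median -1.59, camera adjusted p = 1.0e-38). These included the kinases PLK1 (-2.72 ± 0.17) and AURKA (-1.59 ± 0.11), HMMR (-2.87 ± 0.18) and CDC25B (-1.77 ± 0.12). Replication genes moved less, with 11 of 42 lower, 1 higher (median -0.33, 1 higher and 12 lower adjusted over the list alone, 1 higher and 17 lower at the deposited scaling, 2 higher and 6 lower without the doubted libraries, camera adjusted p = 7.7e-05, 0.33 with an estimated correlation, 0.0959 without GL2 MLN4924 3). These included MCM6 (-1.15 ± 0.16) and UHRF1 (-1.01 ± 0.18). The cyclin E gene CCNE1 (1.09 ± 0.15) rose. CDT1 (-0.51 ± 0.26, adjusted p = 0.146, called at -0.69 at the deposited scaling, -0.78 and called without GL2 MLN4924 1, 0.01 without the doubted libraries) did not pass. BRCA1 (-1.80 ± 0.51, -0.67 and not called without GL2 MLN4924 3, -0.67 without the doubted libraries) includes GL2 MLN4924 3.

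In the same comparison, hypoxia targets rose in 12 of 24 members and fell in 0 (median 0.67, 13 higher and 0 lower adjusted over the list alone, camera adjusted p = 7.7e-09). Among them were ADM (1.72 ± 0.11), MXI1 (2.04 ± 0.11) and the glycolytic gene ALDOC (1.87 ± 0.15). Of the ATF4 and unfolded protein genes, 13 of 28 rose and 0 fell (median 0.55, camera adjusted p = 6.2e-06, 0.136 with an estimated correlation). These included ATF3 (3.48 ± 0.14), CHAC1 (2.13 ± 0.28) and SLC3A2 (1.02 ± 0.11). Ribosome biogenesis genes were higher in 8 of 21 members and lower in 0 (median 0.55, 9 higher and 0 lower adjusted over the list alone, 4 higher and 0 lower at the deposited scaling, camera adjusted p = 6.2e-06, 0.0987 with an estimated correlation). Among them were BYSL (0.99 ± 0.12) and RRP12 (0.89 ± 0.14). Cullin-RING ligase genes rose in 2 of 32 and fell in 0 (median 0.34, 4 higher and 0 lower without the doubted libraries, camera adjusted p = 5.4e-05, 0.233 with an estimated correlation). These were KEAP1 (0.93 ± 0.10), the adaptor that targets NRF2, and FBXW7 (1.35 ± 0.15).

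Genes of the melanocyte lineage and of the interferon response fell as lists. Of the melanocyte genes 4 of 16 fell and 0 rose (median -0.33, camera adjusted p = 0.00606). Among them were SOX10 (-2.47 ± 0.21), S100B (-2.67 ± 0.20) and RAB27A (-0.73 ± 0.16). Interferon-stimulated genes fell in 6 of 25 and rose in 1 (median -0.34, 1 higher and 10 lower at the deposited scaling, camera adjusted p = 0.0014). These included IFI44 (-1.23 ± 0.12), OAS1 (-0.88 ± 0.15, dim) and IFITM1 (-1.02 ± 0.18, dim). MAPK output genes split, 6 of 17 lower and 3 higher (median -0.44, camera adjusted p = 0.00298, 0.178 with an estimated correlation). Among them were SPRY2 (-2.14 ± 0.15) and ETV1 (-1.54 ± 0.16) down and MYC (1.28 ± 0.14) and DUSP5 (0.98 ± 0.09) up. Repair genes of homologous recombination fell in 4 of 26 and rose in 1 (median -0.29, 1 higher and 7 lower at the deposited scaling, camera adjusted p = 0.00809, 0.384 with an estimated correlation, 0.223 without GL2 MLN4924 3). These included CHEK1 (-0.90 ± 0.19) and H2AX (-1.43 ± 0.10). The marker lists of epithelial cells, fibroblasts and leukocytes were not called (camera adjusted p = 0.821, 0.821 and 0.162).

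The largest increases in this comparison were KRTAP3-1 (6.47 ± 0.33, dim, 5.93 without the doubted libraries), GDF15 (5.35 ± 0.21), a secreted stress cytokine on the p53 list, CYP4F11 (5.24 ± 0.43, dim), SUGCT (4.68 ± 0.41, dim), ELAPOR1 (4.61 ± 0.29) and CST7 (4.36 ± 0.53, dim). The largest decreases were IGFBP5 (-6.01 ± 0.39, dim, -7.01 without the doubted libraries), MGP (-5.23 ± 0.43, dim), SDC3 (-4.95 ± 0.26, dim), PDE9A (-4.87 ± 0.44, dim), CEMIP (-4.55 ± 0.39, dim) and CDKN1C (-4.53 ± 0.22, dim). With 3 MLN4924 arrays against 6 DMSO arrays, limma called 3407 of 19775 genes, 2010 higher and 1397 lower. At the deposited scaling the split was 1125 higher and 2152 lower, and without the doubted libraries 3753 genes were called, 2962 of them in common.

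MLN4924 in p53 siRNA cells raised genes of ribosome biogenesis, the ATF4 and unfolded protein list and NRF2 targets, and lowered interferon-stimulated genes. Replication genes rose in 30 of 42 and fell in 0 (median 0.81, 13 higher and 0 lower at the deposited scaling, camera adjusted p = 1.5e-07, 0.219 with an estimated correlation). These included CDT1 (1.61 ± 0.26, adjusted p = 6.0e-06), SLBP (1.25 ± 0.10), CDC6 (1.89 ± 0.21) and CDC25A (2.39 ± 0.30). Ribosome biogenesis genes rose in 19 of 21 and fell in 0 (median 0.96, 9 higher and 0 lower at the deposited scaling, camera adjusted p = 1.7e-12). Among them were NOP2 (1.27 ± 0.09) and RRS1 (1.68 ± 0.14). ATF4 and unfolded protein genes rose in 20 of 28 and fell in 0 (median 1.14, 17 higher and 2 lower at the deposited scaling, camera adjusted p = 5.2e-11). These included ATF3 (4.01 ± 0.14), TRIB3 (2.96 ± 0.19), CHAC1 (4.03 ± 0.28, dim) and SLC3A2 (1.85 ± 0.11). NRF2 targets rose in 12 of 24 and fell in 0 (median 0.67, 13 higher and 0 lower adjusted over the list alone, camera adjusted p = 6.4e-07). Among them were AKR1B10 (2.24 ± 0.12), SRXN1 (2.50 ± 0.14) and GCLM (1.84 ± 0.12). Interferon-stimulated genes fell in 11 of 25 and rose in 0 (median -0.53, camera adjusted p = 1.5e-07). These included IFI44 (-1.55 ± 0.12), IFIT1 (-2.33 ± 0.27, dim) and OAS1 (-1.17 ± 0.15, dim).

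The p53 targets were mixed, 15 of 37 higher and 5 lower (median 0.46, camera adjusted p = 0.0374, 0.458 with an estimated correlation, 0.0594 to 0.0967 without second p53 DMSO 2 or p53 MLN4924 3). GDF15 (2.40 ± 0.21, dim), GADD45A (2.42 ± 0.13), SESN2 (2.45 ± 0.18) and PMAIP1 (2.27 ± 0.20) rose, as did MDM2 (0.67 ± 0.14, not called at the deposited scaling). CDKN1A (0.54 ± 0.15, adjusted p = 0.00363, 0.59 to 0.76 and called without p53 DMSO 2 or second p53 DMSO 3 or p53 MLN4924 2) did not pass. Mitosis genes fell in 8 of 36 and rose in 3 (median -0.16, 0 higher and 18 lower at the deposited scaling, camera adjusted p = 2.9e-04, 0.458 with an estimated correlation). Among them were PLK1 (-1.64 ± 0.17), AURKA (-0.99 ± 0.11) and CCNB1 (-1.23 ± 0.14). Repair genes rose in 11 of 26 and fell in 0 (median 0.49, 5 higher and 2 lower at the deposited scaling, camera adjusted p = 0.0251, 0.458 with an estimated correlation). These included BLM (1.41 ± 0.20) and RAD51AP1 (1.10 ± 0.19). BRCA1 (0.23 ± 0.51, adjusted p = 0.778) did not pass. Rising most were KRTAP3-1 (5.18 ± 0.33, dim), TNIP3 (4.37 ± 0.75, dim), CFAP58 (4.19 ± 0.42, dim) and OLR1 (4.12 ± 0.54, dim). Falling most were MGP (-6.09 ± 0.43, dim), B3GNT7 (-5.74 ± 0.37, dim), SOX2-OT (-4.84 ± 0.58, dim) and SERPINA3 (-4.76 ± 0.23, dim). Over 3 against 6 arrays limma called 5032 genes, 3529 higher and 1503 lower, and 1054 higher and 3450 lower at the deposited scaling.

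The MLN4924 change itself was compared between p53 and GL2 siRNA cells. Among p53 targets the change was lower with p53 siRNA for 24 of 37 and higher for 1 (median -1.11, 3 higher and 24 lower adjusted over the list alone, camera adjusted p = 2.4e-28), by -2.03 ± 0.21 for CDKN1A, -1.27 ± 0.19 for MDM2 and -2.33 ± 0.16 for SESN1. It was higher for 34 of 36 mitosis genes, lower for 0 (median 1.42, 35 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.0e-29). Among them were CDC20 (2.06 ± 0.28) and TOP2A (1.76 ± 0.26). For 33 of 42 replication genes it was higher, lower for 0 (median 1.25, 37 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.2e-23). These included CDT1 (2.12 ± 0.36, 1.60 without the doubted libraries), SLBP (1.21 ± 0.14) and MCM3 (1.65 ± 0.20). Ribosome biogenesis genes differed upward in 10 of 21 and downward in 0 (median 0.60, 3 higher and 0 lower at the deposited scaling, 6 higher and 0 lower without the doubted libraries, camera adjusted p = 1.1e-08). MAPK output genes did so in 7 and 0 of 17 (median 0.64, 8 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.3e-05). These included MYC (2.14 ± 0.19). BRCA1 (2.03 ± 0.72, adjusted p = 0.0589, 2.53 to 2.67 and called without GL2 MLN4924 1 or 2, 0.90 and called without the doubted libraries) did not pass. Largest upward was MGC27382 (5.28 ± 1.27, dim). Largest downward were GASK1B (-4.93 ± 0.38, dim) and SHANK3 (-4.81 ± 1.09, dim). In this test of the difference limma called 2051 genes, 1377 more positive and 674 more negative with p53 siRNA, and 653 more positive and 1421 more negative at the deposited scaling. With the first DMSO set alone as the control 1290 were called.

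Nutlin in GL2 siRNA cells raised p53 targets and lowered genes of replication, mitosis and repair. Among p53 targets 34 of 37 rose and 0 fell (median 1.58, camera adjusted p = 1.2e-43). These included CDKN1A (3.28 ± 0.17, adjusted p = 7.1e-16), MDM2 (2.90 ± 0.16), TP53I3 (3.29 ± 0.12), SESN1 (2.89 ± 0.13) and TP53INP1 (4.24 ± 0.21). Mitosis genes fell in 36 of 36 and rose in 0 (median -4.54, camera adjusted p = 2.3e-79). Among them were CCNB1 (-4.51 ± 0.16), the mitotic cyclin, and AURKA (-3.66 ± 0.13). Replication genes fell in 40 of 42 and rose in 0 (median -3.06, camera adjusted p = 6.5e-60). These included CDT1 (-3.91 ± 0.30) and RRM2 (-5.94 ± 0.19), a subunit of ribonucleotide reductase. Repair genes fell in 20 of 26 and rose in 0 (median -1.86, camera adjusted p = 2.4e-18). Among them were BRCA1 (-3.91 ± 0.58, dim), its partner BARD1 (-2.80 ± 0.20), RAD51AP1 (-5.12 ± 0.22, dim) and FANCI (-3.83 ± 0.23, dim). NF-kB targets rose in 12 of 26 and fell in 2 (median 0.58, camera adjusted p = 6.8e-06). These included the cytokines IL1A (2.55 ± 0.27, dim), CXCL8 (2.55 ± 0.38) and LIF (1.20 ± 0.15).

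The largest increases were ABCA12 (6.57 ± 0.70, dim), CYP4F2 (5.22 ± 0.59, dim), PRAMEF12 (4.89 ± 0.56, dim), SCN4B (4.75 ± 0.64, dim), UNC5B-AS1 (4.75 ± 0.59, dim) and NEURL2 (4.66 ± 0.43, dim). The largest decreases were GINS2 (-7.82 ± 0.30, dim), BIRC5 (-7.17 ± 0.31, dim), ASPM (-7.12 ± 0.24, dim), CDC45 (-6.76 ± 0.23, dim), ESCO2 (-6.62 ± 0.49, dim) and DLGAP5 (-6.21 ± 0.25, dim), several of them genes of replication or mitosis. The limma fit called 3239 genes, 1326 higher and 1913 lower, and 1879 higher and 1463 lower at the deposited scaling.

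In p53 siRNA cells, Nutlin changed 11 genes, 8 higher and 3 lower, and 15 higher and 2 lower at the deposited scaling. CDKN1A (1.87 ± 0.17, adjusted p = 4.2e-08), DDB2 (0.83 ± 0.15, 0.72 to 0.88 and not called without p53 DMSO 2 or 3 or p53 Nutlin 1 or 3) and ACTA2 (1.44 ± 0.13) were higher and RTN4RL2 (-1.95 ± 0.35, dim, -1.91 to -1.22 and not called without p53 DMSO 3 or p53 Nutlin 1 or 3) lower. Of the p53 targets 3 of 37 rose and 0 fell (median 0.12, camera adjusted p = 5.8e-09, 0.203 with an estimated correlation). No member of the mitosis list passed (median -0.21, camera adjusted p = 0.00537, 0.856 with an estimated correlation, 0.0658 without p53 Nutlin 1). MDM2 (0.48 ± 0.16, adjusted p = 0.301), CDT1 (0.20 ± 0.30, adjusted p = 0.884) and BRCA1 (-0.30 ± 0.58, adjusted p = 0.92) did not pass. The count rested on few genes. It was 742 with the second DMSO set as the control and 228 with both sets. It was 87 without the doubted libraries, which enter only through the spread shared by all groups. Leaving out 1 array at a time gave 4 to 32.

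The Nutlin change differed between p53 and GL2 siRNA cells for 1982 genes, 1049 more positive and 933 more negative with p53 siRNA, and 1236 and 963 in that order at the deposited scaling. Of the p53 targets 30 of 37 had a lower change and 0 a higher one (median -1.51, 0 higher and 32 lower adjusted over the list alone, camera adjusted p = 9.8e-40), by -1.40 ± 0.24 for CDKN1A, -2.42 ± 0.22 for MDM2 and -3.16 ± 0.17 for TP53I3. The change was higher for 36 of 36 mitosis genes (median 4.24, camera adjusted p = 2.0e-101), 39 of 42 replication genes (median 2.91, 40 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.5e-72) and 18 of 26 repair genes (median 1.71, camera adjusted p = 2.0e-18). These included CDT1 (4.11 ± 0.42), BRCA1 (3.61 ± 0.83, dim) and RRM2 (5.61 ± 0.27). Largest upward were GINS2 (7.59 ± 0.43, dim) and CDC45 (6.94 ± 0.33, dim). Largest downward were ABCA12 (-6.20 ± 0.99, dim) and SUGCT (-5.87 ± 0.68, dim).

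Daunorubicin in GL2 siRNA cells raised p53 targets and lowered genes of replication, mitosis, repair and sterol synthesis. The p53 targets rose in 27 of 37 and fell in 0 (median 1.23, camera adjusted p = 1.6e-31). Among them were CDKN1A (2.78 ± 0.17, adjusted p = 5.7e-14), MDM2 (1.93 ± 0.16), TP53I3 (2.55 ± 0.12) and SESN1 (2.41 ± 0.13). Of the mitosis genes 36 of 36 fell and 0 rose (median -4.05, camera adjusted p = 1.1e-73). These included CCNB1 (-4.58 ± 0.16). Replication genes fell in 41 of 42 and rose in 0 (median -2.98, camera adjusted p = 1.1e-57). Among them were CDT1 (-3.57 ± 0.30), MCM5 (-3.85 ± 0.17, dim) and RRM2 (-4.16 ± 0.19). Repair genes fell in 19 of 26 with 0 higher (median -1.46, camera adjusted p = 1.9e-16). These included BRCA1 (-3.28 ± 0.58) and RAD51AP1 (-4.04 ± 0.22). Sterol and fatty acid genes fell in 9 of 21 and rose in 0 (median -0.53, camera adjusted p = 5.1e-04). Among them were FDPS (-0.99 ± 0.11), ACAT2 (-1.67 ± 0.21) and SCD (-0.84 ± 0.13). Ribosome biogenesis genes fell in 9 of 21 with 0 higher (median -0.57, 0 higher and 10 lower adjusted over the list alone, camera adjusted p = 3.8e-09). These included FBL (-0.85 ± 0.10) and GAR1 (-0.97 ± 0.10).

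Histones rose in 8 of 20 and fell in 1 (median 0.79, 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.7e-04, 0.143 with an estimated correlation). Among them were H1-2 (1.91 ± 0.16), H2BC21 (2.73 ± 0.33) and H2AC6 (1.95 ± 0.27), on arrays whose actin 5' to 3' ratio was 0.727 to 0.769. The largest increases were ABCA12 (5.79 ± 0.70, dim), SCN4B (4.56 ± 0.64, dim), ALPP (4.18 ± 0.84, dim), GOLT1A (4.17 ± 0.76, dim), SUGCT (4.06 ± 0.48, dim) and PURPL (4.03 ± 0.35, dim). The largest decreases were CDC45 (-6.40 ± 0.23, dim), GINS2 (-6.40 ± 0.30, dim), ASPM (-5.66 ± 0.24, dim), KIFC1 (-5.55 ± 0.56, dim), DEPDC1 (-5.36 ± 0.32, dim) and BIRC5 (-5.36 ± 0.31, dim). In all, limma called 3247 genes, 1283 higher and 1964 lower, and 2055 higher and 1352 lower at the deposited scaling.

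In p53 siRNA cells, daunorubicin raised p53 targets and immediate early genes. This group holds p53 daunorubicin 1, with its low 5' to 3' ratios. The p53 targets rose in 21 of 37 and fell in 1 (median 0.72, 22 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.6e-18). These included CDKN1A (2.74 ± 0.17, adjusted p = 1.7e-12), GDF15 (3.47 ± 0.25, dim) and GADD45A (1.95 ± 0.15). MDM2 (0.55 ± 0.16, adjusted p = 0.012, called at 0.62 at the deposited scaling, 0.59 to 0.79 and called without p53 DMSO 3 or p53 daunorubicin 2) did not pass. Immediate early genes rose in 7 of 14 and fell in 1 (median 0.60, camera adjusted p = 6.6e-06). Among them were EGR1 (2.34 ± 0.24), MAFF (1.21 ± 0.15) and KLF4 (1.21 ± 0.15). Genes of mitosis fell in 25 of 36 and rose in 0 (median -0.93, 0 higher and 27 lower adjusted over the list alone, camera adjusted p = 2.0e-21, 0.0795 with an estimated correlation). These included PLK1 (-2.91 ± 0.20), AURKA (-1.71 ± 0.13) and CCNB1 (-1.82 ± 0.16). ATF4 and unfolded protein genes rose in 11 of 28 and fell in 2 (median 0.36, camera adjusted p = 1.1e-05, 0.158 with an estimated correlation). Among them were ATF3 (2.39 ± 0.16), DDIT3 (2.54 ± 0.30) and ASNS (1.47 ± 0.21).

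Replication genes rose in 5 of 42 and fell in 2 (median 0.18, 8 higher and 1 lower at the deposited scaling, camera adjusted p = 0.033, 0.799 with an estimated correlation, 0.0582 to 0.103 without p53 DMSO 2 or 3 or p53 daunorubicin 1 or 2). These included CDT1 (1.09 ± 0.30, 0.84 and not called without p53 daunorubicin 1) and DTL (1.37 ± 0.30). BRCA1 (0.47 ± 0.58, adjusted p = 0.678, 0.15 without the doubted libraries) did not pass. Histones fell in 7 of 20 and rose in 0 (median -0.85, camera adjusted p = 2.2e-05, 0.0961 with an estimated correlation). Among them were H2BC12 (-1.84 ± 0.12) and H1-2 (-1.07 ± 0.16). Rising most were IL24 (5.18 ± 0.26), C7orf57 (4.73 ± 1.15, dim), SAXO2 (4.01 ± 0.95, dim) and ABCA13 (3.73 ± 0.75, dim). Falling most were MARK2 (-4.25 ± 0.85, dim, -3.23 without the doubted libraries), CRIP2 (-3.78 ± 0.65, dim, -2.08 without the doubted libraries), ALKBH7 (-3.66 ± 0.90, dim, -1.25 without the doubted libraries) and EHBP1L1 (-3.57 ± 0.52, dim, -2.36 without the doubted libraries). From 3 against 3 arrays limma called 2377 genes, 1121 higher and 1256 lower, and 1465 higher and 982 lower at the deposited scaling. A fit of only the groups compared called 51. Without the doubted libraries 612 were higher and 1330 lower, 1355 of them in common with the 2377.

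The daunorubicin change differed between p53 and GL2 siRNA cells for 3035 genes, 1909 more positive and 1126 more negative with p53 siRNA, and 1697 and 1432 in that order at the deposited scaling. It was higher for 41 of 42 replication genes (median 3.06, camera adjusted p = 5.3e-61), 34 of 36 mitosis genes (median 3.12, 36 higher and 0 lower adjusted over the list alone, camera adjusted p = 5.8e-54) and 18 of 26 repair genes (median 1.54, 19 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.5e-18). These included CDT1 (4.66 ± 0.42), BRCA1 (3.75 ± 0.83), RRM2 (4.15 ± 0.27) and CDK1 (4.72 ± 0.32). Of the p53 targets 14 of 37 had a lower change and 3 a higher one (median -0.52, 3 higher and 17 lower adjusted over the list alone, camera adjusted p = 2.8e-07, 0.089 with an estimated correlation). Among them were MDM2 (-1.38 ± 0.22) and TP53I3 (-2.18 ± 0.17). CDKN1A (-0.04 ± 0.24, adjusted p = 0.944) did not pass. Histones had a lower change in 9 of 20 and a higher one in 0 (median -2.04, 0 higher and 12 lower adjusted over the list alone, camera adjusted p = 8.8e-10). These included H1-2 (-2.98 ± 0.23) and H2BC12 (-2.17 ± 0.18). Largest upward were CDC45 (6.78 ± 0.33, dim) and E2F8 (6.47 ± 0.72, dim). Largest downward was ABCA12 (-5.50 ± 0.99, dim). A fit of only the groups compared called 1260. Without the doubted libraries 1508 were more positive and 1416 more negative, 2266 of them in common.

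**Figure D3:**
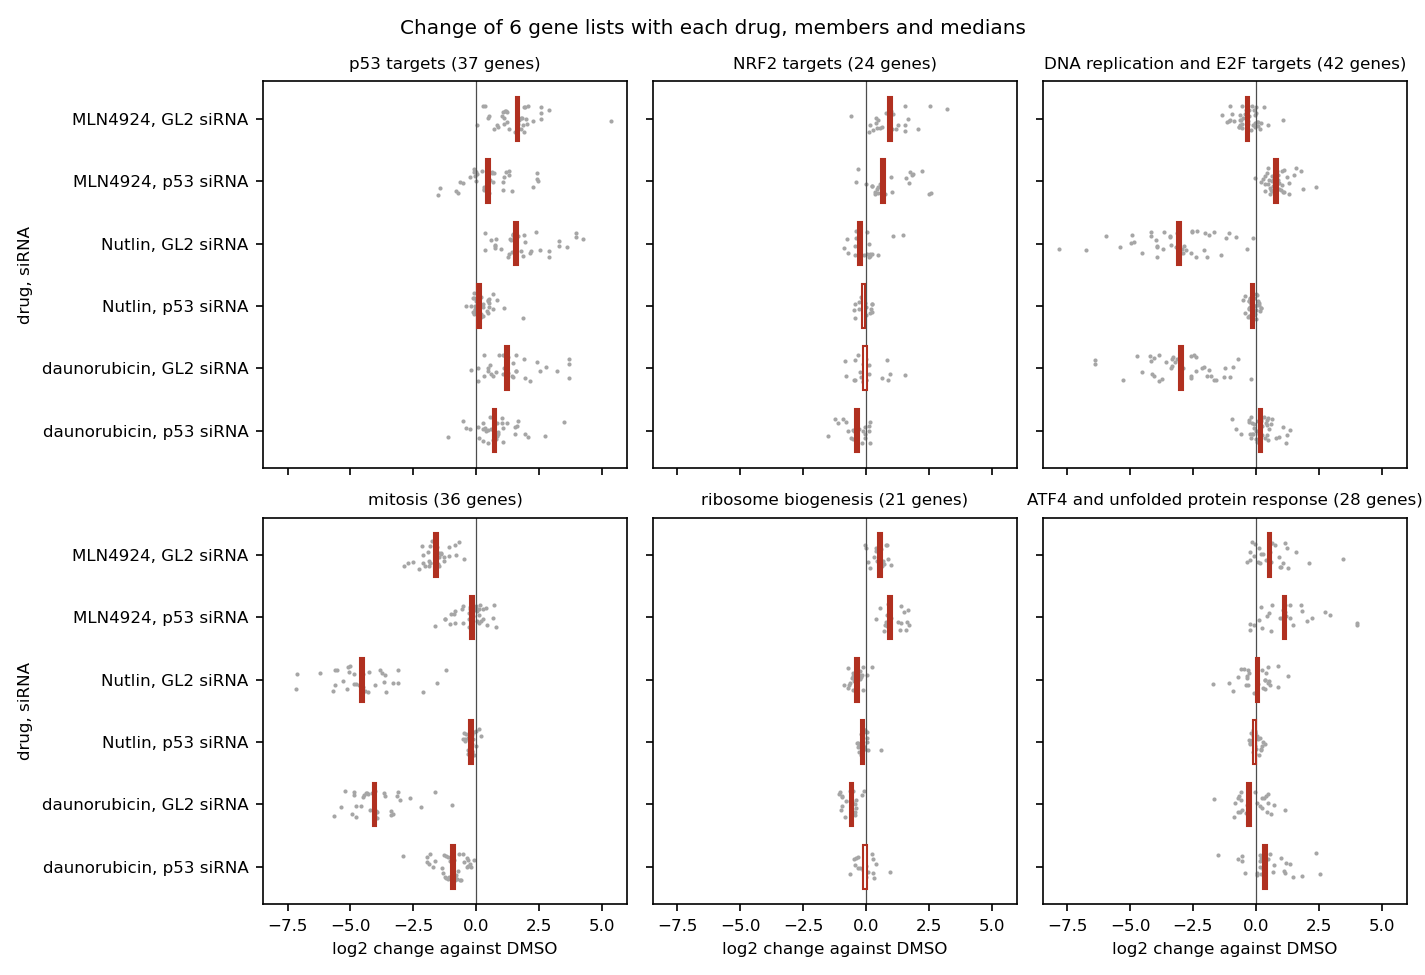
Median log2 change of 6 gene lists (panels) for each drug against DMSO, in GL2 and p53 siRNA cells (horizontal axis, log2 change, grey points for members and strokes for medians). Mitosis genes lie at a median of -4.54 with Nutlin and -1.59 with MLN4924 in GL2 cells, and medians drawn open change sign at the deposited scaling, namely NRF2 targets with Nutlin in p53 siRNA cells (-0.11 to 0.03), ATF4 with Nutlin in p53 siRNA cells (-0.05 to 0.09), NRF2 targets with daunorubicin in GL2 cells (-0.04 to 0.13) and ribosome biogenesis with daunorubicin in p53 siRNA cells (-0.05 to 0.02).

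CDT1 siRNA under DMSO left CDT1 at -2.17 ± 0.26 on the log2 scale (adjusted p = 5.0e-07, 3 against 6 arrays) and CDKN1A at 1.41 ± 0.15. Of the p53 targets 7 of 37 rose and 0 fell (median 0.35, camera adjusted p = 8.0e-09, 0.214 with an estimated correlation). Among them were SESN1 (1.07 ± 0.12) and TNFRSF10B (0.87 ± 0.11), a death receptor. MDM2 (-0.02 ± 0.14, adjusted p = 0.947) did not pass. Replication genes fell in 7 of 42 and rose in 1 (median -0.40, 1 higher and 9 lower adjusted over the list alone, camera adjusted p = 2.3e-07, 0.481 with an estimated correlation). These included GINS1 (-0.95 ± 0.17). Of the mitosis genes 6 of 36 fell and 0 rose (median -0.43, 0 higher and 8 lower adjusted over the list alone, camera adjusted p = 6.7e-08, 0.492 with an estimated correlation). Among them were CDC25B (-0.88 ± 0.12) and AURKA (-0.63 ± 0.11). BRCA1 (-0.51 ± 0.51, adjusted p = 0.615) did not pass, though its arrays lay apart. Rising most were SLC46A3 (3.41 ± 0.58, dim), CNFN (2.88 ± 0.88, dim, 2.66 to 3.04 and not called without second GL2 DMSO 2 or CDT1 DMSO 1 or 2 or 3), LRP2BP (2.66 ± 0.76, dim, 2.53 to 2.76 and not called without CDT1 DMSO 1 or 2 or 3) and ARIH2OS (2.65 ± 0.78, dim, 2.59 to 2.72 and not called without CDT1 DMSO 1 or 2 or 3). Among the largest decreases were COMMD2 (-3.30 ± 0.28), LINC02941 (-2.98 ± 0.47, dim) and C16orf74 (-2.70 ± 0.64, dim). In total 1245 genes were called by limma, 538 higher and 707 lower, and 673 higher and 619 lower at the deposited scaling.

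In CDT1 siRNA cells, MLN4924 raised p53 and NRF2 targets and lowered mitosis genes. The p53 targets rose in 27 of 37 and fell in 0 (median 0.82, camera adjusted p = 2.9e-23). These included CDKN1A (0.87 ± 0.17, adjusted p = 3.8e-04), MDM2 (1.63 ± 0.16), GDF15 (3.57 ± 0.25) and FAS (1.65 ± 0.16). NRF2 targets rose in 11 of 24 and fell in 0 (median 0.62, 12 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.7e-10). Among them were AKR1B10 (2.32 ± 0.14), SRXN1 (1.79 ± 0.16) and TXNRD1 (1.16 ± 0.13). Mitosis genes fell in 28 of 36 with 0 higher (median -1.09, 0 higher and 33 lower adjusted over the list alone, camera adjusted p = 1.7e-29). These included CCNB1 (-1.44 ± 0.16) and AURKA (-1.07 ± 0.13). CDT1 (-0.49 ± 0.30, adjusted p = 0.309) and BRCA1 (-0.32 ± 0.58, adjusted p = 0.792) did not pass. Rising most were LOC101927623 (4.62 ± 0.35, dim), KRTAP3-1 (4.37 ± 0.38, dim), CYP4F11 (4.23 ± 0.50, dim) and VSTM1 (4.11 ± 1.02, dim). Falling most were MGP (-5.65 ± 0.49, dim), CHST6 (-4.96 ± 0.86, dim), IGFBP5 (-4.55 ± 0.45, dim) and SERPINA3 (-4.54 ± 0.27, dim). Called by limma were 2088 genes, 1173 higher and 915 lower, and 806 higher and 1225 lower at the deposited scaling.

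Compared with GL2 cells, the MLN4924 change in CDT1 siRNA cells was lower for 11 of 37 p53 targets and higher for 0 (median -0.53, 0 higher and 15 lower adjusted over the list alone, 0 higher and 17 lower without the doubted libraries, camera adjusted p = 1.6e-17). These included CDKN1A (-1.70 ± 0.22) and SESN1 (-1.14 ± 0.18). Both were already called higher with CDT1 siRNA under DMSO. CDKN1A lay at 9.01 to 9.25 with DMSO in GL2 and 10.44 to 10.61 in CDT1 siRNA cells. With MLN4924 it lay at 11.67 to 11.74 and 11.33 to 11.55. Its smaller change thus went mostly with a higher DMSO level. MDM2 (-0.31 ± 0.21, adjusted p = 0.57) did not pass. Mitosis genes had a higher change in 4 of 36 and a lower one in 0 (median 0.62, 14 higher and 0 lower adjusted over the list alone, 10 higher and 0 lower at the deposited scaling, 7 higher and 0 lower without the doubted libraries, camera adjusted p = 1.4e-14, 0.275 with an estimated correlation). These included PLK1 (1.17 ± 0.26, 1.07 to 1.13 and not called without GL2 MLN4924 3 or CDT1 DMSO 2 or CDT1 MLN4924 1). CDT1 (0.02 ± 0.39, adjusted p = 0.991, -0.50 without the doubted libraries) and BRCA1 (1.48 ± 0.77, adjusted p = 0.434, 0.35 without the doubted libraries) did not pass. Largest upward was GPR183 (4.64 ± 1.20, dim, 3.28 to 4.86 and not called with 1 array left out in 11 of 15 cases). Largest downward were CST5 (-3.71 ± 0.94, dim, -3.82 to -3.27 and not called with 1 array left out in 13 of 15 cases) and FOS (-3.40 ± 0.78, dim, -3.21 to -3.06 and not called without GL2 MLN4924 1 or 2 or CDT1 DMSO 3 or CDT1 MLN4924 2, -3.93 without the doubted libraries). Limma called 241 genes, 103 more positive and 138 more negative, and 245 more positive and 133 more negative at the deposited scaling. The count was 658 without the doubted libraries and 121 to 153 without CDT1 DMSO 1 or 2 or CDT1 MLN4924 1 or 3.

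BRCA1 siRNA under DMSO left BRCA1 at -2.89 ± 0.51 on the log2 scale (adjusted p = 1.6e-04, 3 against 6 arrays), raised p53 targets and lowered sterol and fatty acid genes. CDKN1A rose by 1.86 ± 0.15, and of the p53 targets 17 of 37 rose and 1 fell (median 0.56, camera adjusted p = 6.4e-20). These included SESN1 (1.53 ± 0.12) and TP53INP1 (2.23 ± 0.18). Replication genes fell in 24 of 42 and rose in 1 (median -0.69, 1 higher and 28 lower adjusted over the list alone, camera adjusted p = 4.5e-15, 0.127 with an estimated correlation). Among them were CDT1 (-0.75 ± 0.26, -0.78 to -0.69 and not called with 1 array left out in 8 of 9 cases), MCM5 (-1.09 ± 0.15) and MCM6 (-1.02 ± 0.16). Mitosis genes fell in 31 of 36 with 0 higher (median -0.81, 0 higher and 32 lower adjusted over the list alone, camera adjusted p = 1.7e-23, 0.101 with an estimated correlation). These included MKI67 (-1.35 ± 0.18) and PLK1 (-1.20 ± 0.17). Sterol and fatty acid genes fell in 5 of 21 and rose in 0 (median -0.38, camera adjusted p = 7.1e-05). Among them were SCD (-0.76 ± 0.11) and SREBF1 (-0.66 ± 0.12, -0.52 and not called without BRCA1 DMSO 2). MDM2 (0.56 ± 0.14, adjusted p = 0.00396, called at 0.60 at the deposited scaling, 0.64 and called without BRCA1 DMSO 3) did not pass. Rising most were PXDNL (3.03 ± 0.93, dim, 2.70 to 2.80 and not called without BRCA1 DMSO 1 or 2), NRG4 (2.98 ± 0.78, dim, 2.76 and not called without BRCA1 DMSO 2), MYOZ2 (2.80 ± 0.64, dim) and IL1A (2.71 ± 0.23, dim). Falling most were RAB39B (-3.94 ± 0.50, dim), SFTA1P (-3.28 ± 0.74, dim), CAPSL (-3.26 ± 0.28, dim) and ZNF876P (-3.26 ± 0.78, dim, -2.48 and not called without BRCA1 DMSO 1). In total 1677 genes were called by limma, 813 higher and 864 lower, and 935 higher and 762 lower at the deposited scaling.

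In BRCA1 siRNA cells, MLN4924 raised p53, NRF2 and ribosome biogenesis genes. This comparison holds BRCA1 MLN4924 3. The p53 targets rose in 23 of 37 and fell in 0 (median 0.66, 15 higher and 0 lower at the deposited scaling, camera adjusted p = 3.7e-12). These included CDKN1A (0.75 ± 0.17, adjusted p = 0.00112, not called at the deposited scaling), MDM2 (1.39 ± 0.16), GDF15 (4.42 ± 0.25) and GADD45A (1.30 ± 0.15). NRF2 targets rose in 13 of 24 and fell in 0 (median 0.69, 15 higher and 0 lower adjusted over the list alone, camera adjusted p = 3.7e-10). Among them were AKR1B10 (3.47 ± 0.14), GCLM (2.03 ± 0.14) and SRXN1 (2.02 ± 0.16). Ribosome biogenesis genes rose in 12 of 21 with 0 lower (median 0.66, camera adjusted p = 2.0e-09). These included FBL (0.94 ± 0.10) and BYSL (1.18 ± 0.14). Mitosis genes fell in 30 of 36 and rose in 0 (median -1.07, 0 higher and 31 lower adjusted over the list alone, camera adjusted p = 4.9e-22, 0.0732 with an estimated correlation). Among them were PLK1 (-1.84 ± 0.20) and HMMR (-1.93 ± 0.21). CDT1 (-0.35 ± 0.30, adjusted p = 0.449, -0.79 and called without BRCA1 MLN4924 3) and BRCA1 (0.25 ± 0.58, adjusted p = 0.815, -0.78 and called without the doubted libraries) did not pass. Rising most were KRTAP3-1 (6.59 ± 0.38, dim, 7.11 without the doubted libraries), KISS1 (5.21 ± 0.65, dim), CATSPERD (4.73 ± 0.88, dim) and CYP4F11 (4.73 ± 0.50, dim). Falling most were IGFBP5 (-6.68 ± 0.45, dim), CEMIP (-5.39 ± 0.45, dim), MGP (-5.18 ± 0.49, dim, -4.57 without the doubted libraries) and CDKN1C (-5.17 ± 0.25, dim). Called by limma were 3349 genes, 1936 higher and 1413 lower, and 1000 higher and 1977 lower at the deposited scaling.

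Compared with GL2 cells, the MLN4924 change in BRCA1 siRNA cells was lower for 13 of 37 p53 targets and higher for 0 (median -0.73, 0 higher and 18 lower adjusted over the list alone, 0 higher and 20 lower without the doubted libraries, camera adjusted p = 2.5e-24). These included CDKN1A (-1.82 ± 0.22), SESN1 (-1.72 ± 0.18) and TP53INP1 (-2.21 ± 0.27). MDM2 (-0.55 ± 0.21, adjusted p = 0.194) did not pass. Both doubted MLN4924 libraries enter this difference. Replication genes differed upward in 1 and downward in 0 of 42 (median 0.42, 2 higher and 0 lower adjusted over the list alone, 0 higher and 2 lower without the doubted libraries, median -0.05 without the doubted libraries, camera adjusted p = 5.1e-06, 0.666 with an estimated correlation, 0.078 to 0.124 without GL2 MLN4924 3 or BRCA1 MLN4924 3). CDT1 (0.16 ± 0.39, adjusted p = 0.922, -0.80 and called without the doubted libraries) and BRCA1 (2.05 ± 0.77, adjusted p = 0.199, -0.10 without the doubted libraries) did not pass. Largest upward was MKX (4.62 ± 1.06, dim, 3.52 to 3.96 and not called without GL2 MLN4924 1 or BRCA1 DMSO 1). Largest downward were GUCY1B2 (-3.16 ± 0.76, dim, -2.95 to -2.89 and not called without GL2 MLN4924 1 or BRCA1 DMSO 1 or BRCA1 MLN4924 1 or 2) and P4HA3 (-2.45 ± 0.35, dim). Limma called 368 genes, 125 more positive and 243 more negative, and 177 and 341 in that order at the deposited scaling. The count was 624 without the doubted libraries, 247 of them in common, and 234 without BRCA1 MLN4924 3 alone.

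Under DMSO, p53 siRNA lowered p53 targets and MAPK output genes relative to GL2. CDKN1A fell by 2.09 ± 0.12 on the log2 scale (adjusted p = 1.6e-13, 6 against 6 arrays), and of the p53 targets 11 of 37 fell and 0 rose (median -0.38, 0 higher and 12 lower adjusted over the list alone, camera adjusted p = 2.7e-14). Among them were MDM2 (-0.65 ± 0.11), GDF15 (-2.32 ± 0.17, dim) and DDB2 (-1.04 ± 0.11). MAPK output genes fell in 4 of 17 and rose in 0 (median -0.37, camera adjusted p = 2.5e-08). These included EPHA2 (-0.89 ± 0.10), MYC (-0.93 ± 0.11) and CCND1 (-1.09 ± 0.14). CDT1 (-0.03 ± 0.21, adjusted p = 0.966) and BRCA1 (0.20 ± 0.41, adjusted p = 0.851) did not pass. Rising most were MAP2 (2.88 ± 0.22, dim), CDC42SE2 (2.04 ± 0.17), AQP11 (2.01 ± 0.34, dim) and SEMA3E (1.93 ± 0.22, dim). Falling most were LRRC4B (-3.31 ± 0.44, dim), ESM1 (-2.88 ± 0.18, dim), FRG2EP (-2.70 ± 0.48, dim) and UCA1 (-2.53 ± 0.10). Limma called 787 genes, 339 higher and 448 lower, and 436 higher and 382 lower at the deposited scaling, and 346 with the first set alone.

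The drugs were compared with each other in GL2 cells, as differences of their changes against DMSO. MLN4924 differed from Nutlin upward for replication genes in 39 of 42 and downward in 0 (median 2.73, camera adjusted p = 1.5e-36). Mitosis genes did so in 34 and 0 of 36 (median 2.83, camera adjusted p = 9.6e-34). NRF2 targets did so in 14 and 1 of 24 (median 1.03, 15 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.2e-08). Among single genes CDT1 (3.40 ± 0.33, 3.92 without the doubted libraries), BRCA1 (2.11 ± 0.65, dim, 1.47 to 1.62 and not called without GL2 MLN4924 1 or 2, 3.24 without the doubted libraries), GCLM (2.09 ± 0.16) and SRXN1 (2.16 ± 0.18) were higher with MLN4924, and CDKN1A (-0.71 ± 0.19) and MDM2 (-0.95 ± 0.17) lower. Largest upward were GINS2 (6.86 ± 0.34, dim) and CDC45 (6.49 ± 0.26, dim). Largest downward were IGFBP5 (-6.19 ± 0.50, dim, -7.19 without the doubted libraries) and CEMIP (-5.89 ± 0.50, dim). Limma called 5080 genes, 3362 more positive and 1718 more negative with MLN4924, and 1804 and 3188 in the same order at the deposited scaling.

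MLN4924 differed from daunorubicin upward for replication genes in 40 of 42 and downward in 0 (median 2.57, camera adjusted p = 1.1e-32). Mitosis genes did so in 35 and 1 of 36 (median 2.54, camera adjusted p = 7.9e-26). Ribosome biogenesis genes did so in 20 and 0 of 21 (median 1.05, camera adjusted p = 1.3e-12). CDT1 (3.06 ± 0.33, 3.58 without the doubted libraries) was higher with MLN4924. BRCA1 (1.48 ± 0.65, adjusted p = 0.0845, 2.61 and called without GL2 MLN4924 3), CDKN1A (-0.21 ± 0.19, adjusted p = 0.451) and MDM2 (0.01 ± 0.17, adjusted p = 0.98) did not pass. Largest upward were KRTAP3-1 (6.15 ± 0.42, dim, 5.61 without the doubted libraries) and CDC45 (6.12 ± 0.26, dim). Largest downward were IGFBP5 (-6.71 ± 0.50, dim, -7.70 without the doubted libraries) and SHISA2 (-5.22 ± 0.27). Limma called 5383 genes, 3598 more positive and 1785 more negative with MLN4924, and 1745 and 3428 in the same order at the deposited scaling.

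Nutlin and daunorubicin differed from each other in 455 genes, 213 more positive and 242 more negative with Nutlin, and 189 and 359 in the same order at the deposited scaling. The count was 700 without the doubted libraries, which enter this comparison only through the spread shared by all groups, and 301 without GL2 daunorubicin 3. The p53 targets were higher with Nutlin in 10 of 37 and lower in 0 (median 0.40, 12 higher and 0 lower adjusted over the list alone, camera adjusted p = 9.1e-15). These included MDM2 (0.96 ± 0.16) and TP53I3 (0.74 ± 0.12). Histones were lower with Nutlin in 6 of 20 and higher in 0 (median -0.98, 0 higher and 11 lower adjusted over the list alone, camera adjusted p = 1.5e-11). Among them were H1-2 (-1.59 ± 0.16) and H2AC6 (-1.89 ± 0.27). CDT1 (-0.33 ± 0.30, adjusted p = 0.715), BRCA1 (-0.63 ± 0.58, adjusted p = 0.732, -0.63 and called without the doubted libraries) and CDKN1A (0.50 ± 0.17, adjusted p = 0.114) did not pass. Among the largest upward was CYP4F3 (3.31 ± 0.32, dim). Largest downward were LINC01649 (-3.76 ± 0.98, dim, -3.96 to -3.52 and not called without GL2 daunorubicin 1 or 2 or 3 or GL2 Nutlin 1 or 2 or 3) and ALPP (-3.68 ± 0.84, dim, -3.36 to -3.06 and not called without GL2 daunorubicin 1 or 2).

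Overlaps between comparisons that share control arrays were set against simulations of 2 unchanged groups against the same controls, 20 in all, in which no gene was called in both. Nutlin and daunorubicin in GL2 cells shared 806 higher genes, where independent lists would share 86, and 1422 lower genes, where independent lists would share 190. Their changes correlated across genes at r = 0.795 (simulated 0.499), with a covariance of 0.486 (simulated 0.098), and genes are not independent replicates. Part of the excess may come from the shared first DMSO set, whose 3 arrays could not be split into sets of 2. With MLN4924 set against the second DMSO set, which Nutlin does not use, the 2 drugs shared 362 higher genes (independent 139.7) and 383 lower genes (independent 139.6), with 320 called in opposite directions and a covariance of 0.101 (simulated -0.001). MLN4924 and daunorubicin, likewise, shared 306 higher (independent 135.1) and 365 lower (independent 143.3), with 332 opposite and a covariance of 0.081 (simulated -0.001). CDT1 and BRCA1 siRNA under DMSO shared 244 higher genes (independent 22.1) and 196 lower genes (independent 30.9), with a covariance of 0.124 (simulated 0.048). With the GL2 DMSO sets split between the comparisons, the covariance was 0.057 one way and 0.046 the other.

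The second DMSO set differed from the first in 113 genes, 36 higher and 77 lower over 6 against 6 arrays, and 22 higher and 127 lower at the deposited scaling. The count was 234 without the doubted libraries, none of which is a DMSO array, and 72 without GL2 DMSO 3. Largest upward were LHX8 (1.09 ± 0.17, dim), BBS5 (0.98 ± 0.20, dim), ZNF580 (0.91 ± 0.18) and PRSS35 (0.91 ± 0.18, dim). Largest downward were OR5E1P (-2.07 ± 0.37, dim), EPS8L2 (-1.60 ± 0.29, dim), ANXA10 (-1.57 ± 0.23) and ERICH2-DT (-1.57 ± 0.41, dim, -1.69 to -1.39 and not called with 1 array left out in 11 of 12 cases). CDT1 (-0.23 ± 0.21, adjusted p = 0.67), BRCA1 (-0.27 ± 0.41, adjusted p = 0.828), CDKN1A (-0.19 ± 0.12, adjusted p = 0.498) and MDM2 (0.15 ± 0.11, adjusted p = 0.597) did not pass.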

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

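The tests of exchanged labels, of transfection, of RNA and array quality and of other splits of the arrays were chosen after the result was seen. For the tests of a wrong siRNA label and of the lower median gene, what each outcome would show was written down after the pattern and before the test was run. Each gene, median and count of genes in the next 4 paragraphs is a difference between 2 changes, found by limma's test of that difference.

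The change with MLN4924 differed between p53 and GL2 siRNA cells in 2051 genes. The median difference was -1.11 for p53 targets, 1.25 for replication genes, 1.42 for mitosis genes, -0.32 for interferon-stimulated genes, 0.64 for MAPK output genes, 0.62 for immediate early genes and 0.60 for ribosome biogenesis genes. Single genes were CDKN1A at -2.03, MDM2 at -1.27, SESN1 at -2.33, CDT1 at 2.12, SLBP at 1.21, MCM3 at 1.65, CDC20 at 2.06, TOP2A at 1.76, MYC at 2.14, MGC27382 at 5.28, GASK1B at -4.93 and SHANK3 at -4.81. Of 100 splits 7 called as many genes, at most 2403.

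The change with Nutlin differed between the same siRNAs in 1982 genes, with medians of -1.51 for p53 targets, 2.91 for replication, 4.24 for mitosis and 1.71 for repair genes. Single genes were CDKN1A at -1.40, MDM2 at -2.42, TP53I3 at -3.16, CDT1 at 4.11, BRCA1 at 3.61, RRM2 at 5.61, GINS2 at 7.59, CDC45 at 6.94, ABCA12 at -6.20 and SUGCT at -5.87. Here 8 of 100 splits called as many, at most 3319.

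For daunorubicin the difference covered 3035 genes, with medians of 3.06 for replication, 3.12 for mitosis, 1.54 for repair genes and -2.04 for histones. Single genes were CDT1 at 4.66, BRCA1 at 3.75, RRM2 at 4.15, CDK1 at 4.72, CDC45 at 6.78, E2F8 at 6.47, MDM2 at -1.38, TP53I3 at -2.18, H1-2 at -2.98, H2BC12 at -2.17 and ABCA12 at -5.50. As many genes were called by 7 of 100 splits, at most 3920.

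Between CDT1 and GL2 siRNA the MLN4924 change differed in 241 genes, with a median of -0.53 for p53 targets and -0.42 for hypoxia targets. Single genes were CDKN1A at -1.70, SESN1 at -1.14, PLK1 at 1.17, GPR183 at 4.64, CST5 at -3.71 and FOS at -3.40. As many genes were called by 4 of 100 splits. The highest other split called 1037, several times the real count, and exchanged the MLN4924 arrays of CDT1 and GL2 siRNA whole. Between BRCA1 and GL2 siRNA it differed in 368 genes, with a median of -0.73 for p53 targets. Single genes were CDKN1A at -1.82, SESN1 at -1.72, TP53INP1 at -2.21, MKX at 4.62, GUCY1B2 at -3.16 and P4HA3 at -2.45. As many were called by 2 of 100 splits. The real grouping holds the doubted pair, so chance is not judged from this share. The other split called 1670, several times the real count. For MLN4924 arrays it mirrors the split with the doubted pair in each other's group.

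Splits of a difference between changes keep part of the real effect where they leave the treated arrays apart, as labelled or exchanged. For MLN4924, Nutlin and daunorubicin between p53 and GL2 siRNA, and MLN4924 between CDT1 and GL2 siRNA, every split with as many genes did so (7 of 7, 8 of 8, 7 of 7 and 4 of 4). Splits that mixed the treated arrays called at most 16, 87, 880 and 11 genes. MLN4924 less Nutlin, 5080 genes, and less daunorubicin, 5383, had 14 and 7 of 100 splits as large, at most 5554 and 5934. The treated arrays were apart in all of these, and mixed splits called at most 2 and 3. For these 6 counts the share of splits is thus largely set by the design and says nothing on chance. No other split was as large for MLN4924 in GL2 (3407 against at most 1399 in 84 splits) and p53 siRNA cells (5032 against 1553). The same held for CDT1 siRNA (1245 against 542), BRCA1 siRNA (1677 against 584), p53 siRNA (787 against 275) and the DMSO sets (113 against 39). A chance difference between cultures or sets stays possible, as replicates may not be separate cultures. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real value and the highest other were 3239 and 1 for Nutlin in GL2 cells, 11 and 1 for Nutlin in p53 siRNA cells, 3247 and 1 for daunorubicin in GL2 cells and 2377 and 204 in p53 siRNA cells. They were 2088 and 1 for MLN4924 in CDT1 siRNA cells, 3349 and 2 in BRCA1 siRNA cells, and 455 and 2 for Nutlin less daunorubicin.

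A pair of MLN4924 libraries showed BRCA1 levels that go against their labels. On 1676 genes called between BRCA1 and GL2 siRNA, with BRCA1 left out, on a scale from 0 for the other GL2 MLN4924 libraries to 1 for the other BRCA1 siRNA ones, GL2 MLN4924 3 lay at 0.99 and BRCA1 MLN4924 3 at 0.04, which is consistent with an exchange of the pair. A failed transfection of BRCA1 MLN4924 3 alone is argued against by BRCA1 in GL2 MLN4924 3, at -3.25 from the lower of its group. Degraded RNA is argued against by the lower actin 5' to 3' ratio of the pair, 0.888, within the 0.872 to 0.918 of the other 10 MLN4924 arrays. The design gives no biological explanation to test, and the place of an exchange, before or after hybridisation, stays open.

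The library p53 daunorubicin 1 stood apart from its group in the 5' signal of control genes. Its middle to 3' ratio was 0.418 for actin and 0.307 for GAPDH, against 0.751 to 0.980 and 0.782 to 0.899 on the other 41 arrays, and its 5' to middle ratio 0.0281 and 0.166, against 0.851 to 1.07 and 1.19 to 1.45. Signal thus fell at both steps in both genes, which is consistent with degraded RNA or short cDNA, and these were not told apart. A dim or badly hybridised array is argued against by the BioB spike signal of 133.6, within the range of the other arrays, and a wrong siRNA label by a position of 0.78 on 787 genes, nearer to the other p53 siRNA daunorubicin libraries at 1 than to GL2 daunorubicin at 0. No biological explanation was tested.

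At the deposited scaling the median gene was lower on MLN4924 arrays. Median changes in GL2 cells were -0.25, -0.16, -0.08 and 0.02 over 4 equal sets of genes from dimmest to brightest, and -0.37, -0.33, -0.23 and 0.03 in p53 siRNA cells, which is consistent with lower signal of dim probe sets near background. The brightest 5 percent of probe sets held 55.71% to 58.1% of signal on MLN4924 arrays and 53.01% to 58.4% on DMSO arrays. These ranges overlap, so a larger share stays open. A lower level of weakly expressed genes in treated cells was not tested and stays open.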

How the results depend on the processing

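The settings that leave out the doubted libraries and the deposited scaling were chosen after the result was seen, and the others were planned. Centring each array on its median was listed as an alternative, and the fixed rule made it the main setting. The cause of the changes below was not tested.

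With adjusted p under 0.01 and at least 2-fold the counts of genes were for MLN4924 in GL2, p53, CDT1 and BRCA1 siRNA cells 1243, 1778, 688 and 1203, for Nutlin in GL2 and p53 siRNA cells 1338 and 4, for daunorubicin there 1327 and 751, for the differences between p53 and GL2 siRNA with MLN4924, Nutlin and daunorubicin 619, 898 and 1325, for those of CDT1 and BRCA1 siRNA with MLN4924 52 and 104, for CDT1, BRCA1 and p53 siRNA under DMSO 276, 441 and 167, for MLN4924 less Nutlin, MLN4924 less daunorubicin and Nutlin less daunorubicin 2268, 2412 and 111, and for the DMSO sets 16. With no fold limit they rose past 1.5 times to 5710, 3153 and 5029 for MLN4924 in GL2, CDT1 and BRCA1 siRNA cells. For CDT1, BRCA1 and p53 siRNA they rose to 2397, 2919 and 2036, and for the DMSO sets to 287.

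Array weights gave 177 for Nutlin in p53 siRNA cells, 3145 for the p53 siRNA difference with Nutlin, 966 for the CDT1 siRNA difference, 697 for the BRCA1 siRNA difference, 835 for Nutlin less daunorubicin and 456 for the DMSO sets, and their estimate stopped before its tolerance was reached. With only the compared groups in the fit Nutlin and daunorubicin in p53 siRNA cells had 1 and 51. The p53 siRNA difference with daunorubicin had 1260, the CDT1 siRNA difference 380 and the DMSO sets 178. Without the 3 doubted libraries Nutlin in p53 siRNA cells had 87, Nutlin less daunorubicin 700 and the DMSO sets 234. The CDT1 and BRCA1 siRNA differences had 658 and 624. Without the pair of doubted MLN4924 libraries all 20 counts stayed within 1.5 times.

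The count for Nutlin in p53 siRNA cells was 228 with both DMSO sets as control, 742 with the second set, and 17 at the deposited scaling. The first set as control gave 1290 for the p53 siRNA difference with MLN4924 and 346 for p53 siRNA, and 3 shifted lists for the BRCA1 siRNA difference. For the CDT1 siRNA difference the deposited scaling gave 378 genes and the mean of all probe sets 159. The mean of probe sets gave 7 shifted lists for Nutlin in p53 siRNA cells. Quantile normalization gave 8 for MLN4924 in p53 siRNA cells and 1 for Nutlin in p53 siRNA cells. Leaving out dim genes, a pseudocount of 16, and a trend with robust variances kept all 20 gene counts within 1.5 times.

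With an estimated correlation in camera, MLN4924 in GL2, p53, CDT1 and BRCA1 siRNA cells had 6, 5, 5 and 4 shifted lists. Nutlin and daunorubicin in p53 siRNA cells had 0 and 2, and the p53 siRNA difference with daunorubicin 4. The CDT1 and BRCA1 siRNA differences had 2 and 1, and CDT1, BRCA1 and p53 siRNA 0, 2 and 3. MLN4924 less Nutlin, MLN4924 less daunorubicin and Nutlin less daunorubicin had 5, 6 and 4, and the DMSO sets 0.

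Genes and lists called in either setting changed or lost their sign, for lists that of the test, in 8 cases. List medians that turn sign at the deposited scaling are not among these. Under quantile normalization the proteasome median was -0.09 in the p53 siRNA difference with MLN4924, 0.00 with Nutlin in p53 siRNA cells and -0.01 between the DMSO sets. Without the 2 or the 3 doubted libraries BRCA1 moved to -0.78 with MLN4924 in BRCA1 siRNA cells, and the median of replication genes to -0.05 in the BRCA1 siRNA difference. There CDT1 moved to -0.80 without the 3.

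The replicate numbers of the titles did not pair the arrays: over 91 pairs of groups per number the mean correlation of residuals was -0.002, 0.003 and -0.008. With the replicate number as a block all 20 gene counts and all 20 list counts stayed within 1.5 times, and 404 of 408 single-gene results were kept. With the block within each set Nutlin in p53 siRNA cells had 5 genes.

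Leaving out 1 array at a time gave gene counts for MLN4924 in GL2, p53, CDT1 and BRCA1 siRNA cells 3150 to 3567, 4573 to 5047, 1838 to 2046 and 3079 to 3288, for Nutlin in GL2 and p53 siRNA cells 2963 to 3077 and 4 to 32, for daunorubicin there 2975 to 3108 and 1831 to 3085, for the differences between p53 and GL2 siRNA with MLN4924, Nutlin and daunorubicin 1382 to 2180, 1677 to 1990 and 2609 to 3817, for those of CDT1 and BRCA1 siRNA with MLN4924 121 to 227 and 234 to 382, for CDT1, BRCA1 and p53 siRNA under DMSO 952 to 1267, 1415 to 1656 and 712 to 804, for MLN4924 less Nutlin, MLN4924 less daunorubicin and Nutlin less daunorubicin 4645 to 5305, 4839 to 5692 and 301 to 454, and for the DMSO sets 72 to 117. Counts left the 1.5-fold range for the CDT1 siRNA difference (149 without CDT1 DMSO 1, 121 without CDT1 DMSO 2, 143 without CDT1 MLN4924 1 and 153 without CDT1 MLN4924 3), the BRCA1 siRNA difference (234 without BRCA1 MLN4924 3), Nutlin in p53 siRNA cells (4 without p53 DMSO 3, 32 without p53 Nutlin 2 and 5 without p53 Nutlin 3), Nutlin less daunorubicin (301 without GL2 daunorubicin 3) and the DMSO sets (72 without GL2 DMSO 3). Shifted lists, in the order of those gene counts, were 13 to 15, 12 to 14, 9 to 12 and 11 to 13 for MLN4924. They were 6 to 7 and 4 to 5 for Nutlin, 8 to 9 and 9 to 11 for daunorubicin. For the differences between siRNAs they were 10, 6 to 8, 8 to 10, 6 to 10 and 3 to 8. Under DMSO they were 8, 8 to 9 and 8 to 11 for the siRNAs and 1 to 4 for the sets. Between drugs they were 14 to 15, 12 to 13 and 11 to 13. Shifted lists left the 1.5-fold range for the BRCA1 siRNA difference (3 without GL2 MLN4924 3). For the DMSO sets they were 1 without GL2 DMSO 1, p53 DMSO 2 or second GL2 DMSO 3.

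Among single genes, leaving out 1 array ended 90 calls and added 11, and 3538 results were kept. Among lists it ended 80 shifts and kept 1798. Calls ended in 24 cases with only the compared groups, 22 with the mean of probe sets, 17 with the pseudocount, 13 with the first and 12 with the second DMSO set as control, 7 with the block within each set, 4 with the replicate block, 5 with quantile normalization, 2 at the deposited scaling, 2 without the doubted MLN4924 pair and 1 with the trend.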

Other observations

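MLN4924 changed a set of genes in the same direction in all 4 siRNA backgrounds. Values here are log2 changes with GL2, p53, CDT1 and BRCA1 siRNA in that order, and these genes were chosen after their values were seen, from genes called in each background, at both scalings, without the doubted libraries, and in the tests of difference from Nutlin and from daunorubicin. Here "dim" marks a gene with any of the 14 groups under a signal of 31.9. Lower were the transcription factor genes SOX10 (-2.47, -3.02, -2.39 and -2.01), FOXD3 (-2.28, -4.60, -2.12 and -3.78, dim), TFAP2B (-2.06, -2.39, -2.53 and -2.57) and SOX2 (-2.72, -1.97, -2.52 and -2.44), as were the receptor gene ERBB3 (-2.94, -3.07, -2.68 and -3.35) and S100B (-2.67, -3.57, -2.58 and -3.12). Higher were CCN1 (1.49, 2.29, 2.04 and 2.02), CCN2 (1.65, 2.18, 2.27 and 2.13), ANKRD1 (3.16, 3.58, 2.47 and 2.97, dim) and AMOTL2 (1.41, 1.71, 1.42 and 2.20). Higher as well were SRXN1 (2.06, 2.50, 1.79 and 2.02), OSGIN1 (2.53, 2.57, 2.31 and 2.24, dim) and ATF3 (3.48, 4.01, 2.45 and 3.23).

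Called higher in all 4 backgrounds were 482 genes, where independent lists would share 2.1, and lower 432, where they would share 0.4. The 4 comparisons use separate treated and DMSO arrays. At the deposited scaling these were 234 higher and 677 lower, and at both scalings 234 higher and 432 lower. Without the doubted libraries 505 were higher and 463 lower, 451 and 408 of them in common with the full set. Of the genes higher in all 4 backgrounds, 36 were called the same way with both Nutlin and daunorubicin in GL2 cells and 51 the opposite way, and of the lower genes 58 and 67. The genes that met every condition above were 204 higher and 323 lower. Lists that share effects of any kind exceed the independent value, and no explanation was tested.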
